A study of Drosophila melanogaster with 8 samples.

How the data were processed

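The series holds 8 RNA-seq libraries from heads of adult Drosophila melanogaster in which FBXO11 was or was not knocked down in neurons by RNA interference. The titles in the labels place 3 libraries in the control group, 3 in RNA1 and 2 in RNA2, and these titles defined the groups. The genotype entries give a single name to the 3 RNA1 libraries but different names to the 2 RNA2 libraries, KD2 and KD3, so each RNA2 library was also left out in turn. Every library carries batch 1. RNA was extracted with a lipid tissue kit and Trizol and made into stranded, poly(A)-selected libraries, per the labels' protocols. Nothing in the labels says that the replicates of a group came from separate pools of flies, so the p-values here measure only the spread between these samples, which may be technical.

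The authors deposited a table of whole-number read counts per gene with no normalization. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, trimmed with cutadapt 1.18, inspected with FastQC 0.11.8, mapped to build BDGP6 with STAR 2.6.1 and handled with SAMtools 1.8, and the notes also name DESeq2 1.24.0. The tool that assigned reads to genes, its strand setting and the annotation release are not given in the sources used here. Genes that overlap another gene on the opposite strand, and near-identical copies within gene families, are therefore reported as uncertain. Among the genes named, this applies on the opposite strand to CG6356, Obp44a, ninaB, DptB, Or45b, Cpr65Au, santa-maria, Pdh, PGRP-LF, PGRP-SD, Hsp83, RpS20, RpL39, Gnmt, Irk3, Vmat, DIP-zeta, Lsp2, apolpp, LysD, Ag5r, p53, Cyp4aa1, dbr and the antisense RNAs. ChAT, Teh3, RpS27A, dbr and lncRNA:CR45345 overlap a gene on their own strand. The table has 17676 genes, of which 17549 were matched to a symbol and 127 were not, and 2507 genes had no count in any library. Coordinates come from an Ensembl annotation of BDGP6, whose release may differ from the one the authors used.

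Total counts per library were 38933684, 41589222 and 39051500 in the controls, 36809556, 36132003 and 32434805 in RNA1, and 35832058 and 33369175 in RNA2. Counts came from amplified reads without molecular identifiers, so the floor of 3 counts per library that stands in for a count of 0 covers counting error only. Where a group had counts but 3 or fewer per library on average, a named gene that passed is given as the ratio of pooled counts per total count, with an exact (Clopper-Pearson) 95% interval for counting error only, because its fitted fold change depends on the prior count. Pairs of libraries from the same group correlated at r = 0.983 to 0.993 across genes (7 pairs) and pairs from different groups at 0.969 to 0.988 (21 pairs); genes are not independent replicates. Within groups, chi-square per degree of freedom lay between 23.6 and 69.7, so no pair of libraries agreed within sampling noise and each was counted as 1 replicate.

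Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 3 groups (minimum count 10, minimum total 15), which left 11081, and libraries were scaled by TMM. One quasi-likelihood model with robust dispersion was fitted to all 8 libraries with a mean per group and no covariate. It gave the contrasts RNA1 against control, RNA2 against control and RNA2 against RNA1 from two-sided F tests. The biological coefficient of variation was 0.143. FDR is edgeR's Benjamini-Hochberg value over all genes tested, and a gene is said to rise or fall when its FDR was under 0.05. Levels are CPM (read counts scaled to a common library size), computed here from the deposited counts with TMM scaling and given as mean ± SD. Log2 fold changes carry a standard error (SE), taken as the absolute log2 fold change divided by the square root of its F statistic. This SE is approximate and can be too small where a group has few counts.

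A set of 53 gene lists was fixed before the data were examined, as were the groups, the tests and the alternatives, except where an alternative is said to have been added later. Of their entries, 1655 were matched and 22 were not, and 47 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Another 5 lists had fewer tested members, and 1 had no entry matched. Camera with a correlation estimated per list was run beside it, as was fry, which asks whether the genes of a list move on balance one way. With an estimated correlation 0 of 47 lists passed in either knockdown. The lowest adjusted p was then 0.458 in RNA1 and 0.523 in RNA2, and 4 and 3 lists had an unadjusted p under 0.05. This form of camera was weaker even where the estimate lay near or below the preset. In RNA1 the Toll and Imd list had an estimated correlation of 0.0136, yet its unadjusted camera p went from 0.0017 to 0.0289. For chemosensory receptors (estimate 0.0003) it went from 0.0126 to 0.0255. Failing this form therefore does not show that a call came from genes that vary together.

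Genes were named by a rule fixed in advance. It takes FBXO11 and, per contrast, up to 6 genes in each direction with the largest fold change, a symbol that is not a CG or CR number, a mean CPM of at least 1 and no overlap between replicates. The gene with the largest fold change in each direction is added whatever its symbol. Up to 4 members of each list with the smallest p in that contrast and, for genes changed alike in both knockdowns, 10 genes with the smallest p-values were taken as well. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen.

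The alternatives were DESeq2 size factors or library totals in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter filter (CPM of at least 5 in at least 2 libraries), fits to only the groups compared, the replicate number as a block, removal of the 20 most abundant genes, a 2-fold minimum, an FDR under 0.01, and each library left out in turn. The pipeline was tested on simulated counts for the 11081 genes, in 3 runs with 200 genes changed in each. Of genes changed 1.5-, 2-, 4- and 8-fold, 49.3%, 74%, 89.3% and 99.3% were recovered in RNA1 against control, 39.3%, 68%, 88% and 97.3% in RNA2 against control, and 27.3%, 74%, 87.3% and 96% in RNA2 against RNA1. Unchanged genes were called at 0.17%, 0.114% and 0.0643% in these contrasts. A simulated 1.5-fold rise of all 77 tested nuclear-encoded oxidative phosphorylation genes was called in 3 of 3 runs against control for both knockdowns. Smaller shifts of a list were not simulated. Each knockdown had 141 list tests, those of the shifted list included, in which 1 unshifted list was called for RNA1 and 0 for RNA2. Genes were simulated independently of each other, so this does not measure false calls for lists whose genes vary together.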

Results

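RNA from the heads of adult flies was sequenced to ask what neuronal loss of FBXO11 does to the transcriptome. FBXO11 is an F-box protein, the substrate-recognition subunit of a cullin-RING ubiquitin ligase that marks proteins for degradation by the proteasome. The groups were 3 control libraries, 3 libraries of the knockdown RNA1 and 2 of the knockdown RNA2, in all 8 libraries with 32434805 to 41589222 counted reads. The genotype entries of the RNA2 libraries differ (KD2 and KD3) although their titles agree, and they are treated here as 2 replicates of RNA2. Control and knockdown libraries share no genotype entry. A difference of genetic background therefore cannot be told apart from the knockdown in any comparison with control. Among the most abundant transcripts were ninaE and Arr2, the rhodopsin and arrestin of the photoreceptors. The first principal component held 40.6% of the variance and placed the 5 knockdown libraries on one side and the 3 controls on the other, and the second held 17.9%.

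FBXO11 (FBgn0037760; BDGP6 3R:9803486-9809368, minus strand, overlapping no other gene) was lower in every knockdown library than in every control. The control libraries held 108, 102.9 and 97.4 CPM, the RNA1 libraries 39.7, 42.5 and 37.5 CPM, and the RNA2 libraries 44.8 and 52.7 CPM. Group means were 103 ± 5.29 CPM (SD, n = 3) in control, 39.9 ± 2.52 CPM (n = 3) in RNA1 and 48.8 ± 5.54 CPM (n = 2) in RNA2. RNA1 retained 38.8% of the control level (log2 -1.37 ± 0.09 SE, edgeR FDR 4.9e-05) and RNA2 47.5% (log2 -1.08 ± 0.10, FDR 0.00054). Both RNA2 libraries lay above all 3 RNA1 libraries, by log2 0.29 ± 0.09 on average, with an edgeR p of 0.0125 for this gene alone and an FDR of 0.44 over all genes. Heads contain glia, muscle, fat body and epidermis beside neurons, so these levels are averages over all of those cells.

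**Figure D1:**
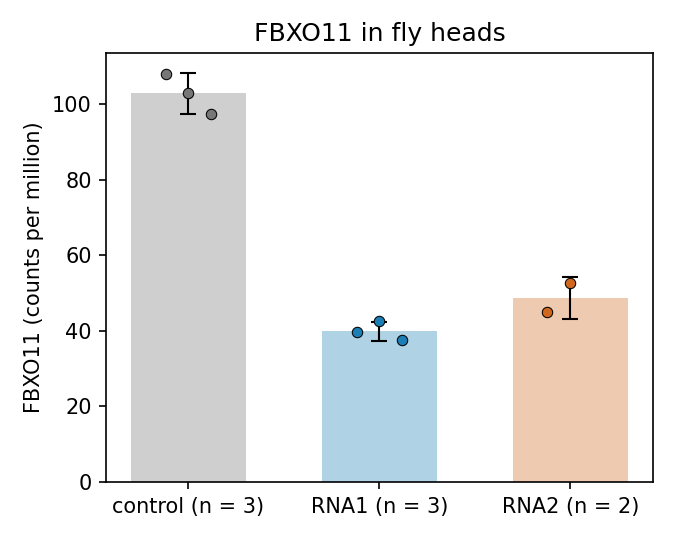
FBXO11 in CPM (vertical axis) in the control, RNA1 and RNA2 groups. Each point is a library, bars are group means and error bars are 1 SD; the control libraries lie between 97.4 and 108 CPM and the knockdown libraries between 37.5 and 52.7 CPM.

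The comparison of RNA1 with control asks which transcripts change when FBXO11 is reduced in neurons, and genes of the innate immune response were among those with large rises. DptA, an antibacterial peptide induced through the Imd pathway, went from 8.23 ± 6.01 to 345 ± 164 CPM (log2 5.39 ± 0.71, FDR 0.01, 3 against 3 libraries). The infection-induced genes IBIN and edin rose by log2 6.20 ± 0.78 (FDR 0.0082) and 6.03 ± 0.61 (FDR 0.0033). Of the 33 tested antimicrobial peptides, 25 rose and 3 fell (28 and 3 adjusted over the list alone). Drs, the antifungal drosomycin, rose by log2 3.53 ± 0.15 (FDR 6.4e-06), and the secreted bomanins BomT2 and BomS5 rose by 1.51 ± 0.12 and 1.97 ± 0.16. The members that fell were Listericin (log2 -0.79), Drsl4 (-0.96) and Drsl5 (-1.09), named because they were so few, after their values were seen. Camera, which sets a list against all other genes, ranked the peptides high at its preset correlation (adjusted p = 1.27e-16) but not with an estimated correlation (adjusted p = 0.458). Fry, which asks whether the peptides moved on balance one way and does not compare them with other genes, gave an adjusted p of 0.0073. Cecropins, attacins and bomanins have close copies between which reads can be split, and DptB (log2 4.83 ± 0.47) overlaps a gene on the other strand.

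Some genes of the Toll and Imd pathways, which detect microbes and regulate the immune response, also rose in RNA1. Of 23 Toll and Imd pathway genes, 8 rose (8 rose and 1 fell adjusted over the list alone). PGRP-LC, the Imd receptor, rose by log2 0.34 ± 0.06, PGRP-LF, a membrane protein that restrains Imd signalling, by 0.79 ± 0.13 and the NF-kappaB factor Rel by 0.61 ± 0.11. The amidase PGRP-SC2, which degrades peptidoglycan, rose by log2 4.78 ± 0.71. The Toll and Imd list passed camera (adjusted p = 0.00911; adjusted p = 0.458 with an estimated correlation). Some markers of fat body and hemocytes, which make these peptides, rose as well. Of 13 fat body markers, 3 rose: bmm, a triglyceride lipase (log2 0.84 ± 0.14), Gnmt (2.05 ± 0.34) and Mtp (0.46 ± 0.10). The takeout gene to fell by 1.26 on the log2 scale, and 6 markers rose and 1 fell adjusted over the list alone. The fat body list passed camera at an adjusted p of 0.0138, or 0.0583 without RNA1 replicate 3 (adjusted p = 0.738 with an estimated correlation). Of 12 hemocyte markers, 4 rose, and 5 adjusted over the list alone. They were the scavenger and phagocytic receptors Sr-CI (log2 1.34 ± 0.19), eater (1.29 ± 0.24) and NimC1 (1.13 ± 0.23) and the hemolymph protein Hml (1.09 ± 0.25). The hemocyte list did not pass camera (adjusted p = 0.0648), except without control replicate 1 (0.0464) or RNA1 replicate 1 (0.00144). In the 3 RNA1 libraries the median fat body marker lay at log2 0.17, 0.703 and 0.672 above the control mean, and the median antimicrobial peptide at 1.5, 1.91 and 1.57. The median hemocyte marker lay at -0.0881, 0.257 and 0.295.

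Several genes of neurons, glia and photoreceptors fell in RNA1. Of all 11081 tested genes 582 fell, a share that the dpr and DIP genes below hardly exceed. Of 22 genes for making and loading transmitters, 4 fell (also 4 adjusted over the list alone). ChAT, which makes acetylcholine, fell by 0.41 ± 0.07 on the log2 scale (FDR 0.0056) and the serotonin transporter SerT by 0.53 ± 0.09. The vesicular transporters VGAT and Vmat stood at log2 -0.39 ± 0.08 and -0.32 ± 0.08. The transmitter list passed camera at an adjusted p of 0.000858 (adjusted p = 0.56 with an estimated correlation; fry adjusted p = 0.0316). Of 17 glial genes 4 fell, zyd, wrapper, bnb and Gli (log2 -0.54, -0.62, -0.59 and -0.49), and 6 adjusted over the list alone. For the glial list camera gave an adjusted p of 0.00725, or 0.0582 without RNA1 replicate 1 (adjusted p = 0.738 with an estimated correlation). Of 32 phototransduction genes 6 fell (7 fell and 1 rose adjusted over the list alone). Among them were ninaB, which makes the retinal chromophore (log2 -0.66 ± 0.08), the carotenoid receptor santa-maria (-0.42 ± 0.07), Pdh (-0.54 ± 0.09) and Cpn (-0.57 ± 0.11). The phototransduction list passed camera (adjusted p = 0.00379; adjusted p = 0.738 with an estimated correlation). Of 10 activity-regulated genes 3 fell, and 4 adjusted over the list alone. These were the Egr homologue sr (log2 -1.41 ± 0.22), the JNK phosphatase puc (-0.37 ± 0.08) and the Fos homologue kay (-0.32 ± 0.07). The activity-regulated list also passed camera (adjusted p = 0.00725; adjusted p = 0.738 with an estimated correlation). Among 37 axon guidance genes Nrg, caps and Sema5c fell (log2 -0.38, -0.28 and -0.48; 3 adjusted over the list alone). That list had a camera adjusted p of 0.00241 (adjusted p = 0.738 with an estimated correlation). Among 32 dpr and DIP adhesion genes DIP-epsilon and DIP-zeta fell (log2 -0.49 and -0.38; 1 adjusted over the list alone). Their list had a camera adjusted p of 0.0277, or 0.0892 without control replicate 1 and 0.375 without RNA1 replicate 3 (adjusted p = 0.83 with an estimated correlation). In the synaptic vesicle cycle edgeR called 0 of 24 genes, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.0647). Camera passed the synaptic vesicle list without control replicate 2 or 3 (adjusted p = 0.0403 and 0.0467) and without RNA1 replicate 1 or 2 (0.017 and 0.0139). In RNA1 replicates 1, 2 and 3 the median axon guidance gene lay at log2 -0.0896, -0.0638 and -0.23 against the control mean. The dpr and DIP median lay at -0.0615, -0.0453 and -0.216 and the synaptic vesicle median at -0.0263, -0.0125 and -0.198. Replicate 3 was thus lowest for these lists and highest for digestive enzymes (2.22), while the glial median was lowest in replicate 1 (-0.319).

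More cuticle and detoxification genes fell than rose in RNA1, and 14 of 86 cytosolic ribosomal protein genes rose. Of 56 cuticle genes 10 fell and 2 rose (16 and 3 adjusted over the list alone). TwdlT stood at log2 -1.22 ± 0.15, Cpr67B at -0.76 ± 0.11 and Cpr65Au at -0.88 ± 0.13. The cuticle list passed camera (adjusted p = 6.42e-05; adjusted p = 0.738 with an estimated correlation). Of 78 cytochrome P450 genes 13 fell and 4 rose (18 and 11 adjusted over the list alone), led by Cyp6a2 at log2 -1.65 ± 0.15. The P450 list did not pass camera (adjusted p = 0.267), and its median and mean differed in sign (-0.0252 and 0.038). Of 32 glutathione S-transferases 5 fell and 2 rose (7 and 2 adjusted over the list alone), with GstD2 at -1.52 ± 0.19 (camera adjusted p = 0.239). Of 25 UDP-glycosyltransferases 6 fell (8 adjusted over the list alone), with Ugt35C1 at -0.96 ± 0.12. The glycosyltransferase list passed camera at an adjusted p of 0.0382 (adjusted p = 0.738 with an estimated correlation). Its call was lost without control replicate 3 (0.0579), RNA1 replicate 3 (0.086), RNA2 replicate 1 (0.0562) or RNA2 replicate 2 (0.0655). Of 86 cytosolic ribosomal proteins 14 rose (14 adjusted over the list alone), including RpS3A at log2 0.44 ± 0.08 and RpL39 at 0.45 ± 0.09, and the list median was 0.169. The ribosomal list passed camera (adjusted p = 1.62e-05; adjusted p = 0.83 with an estimated correlation). Digestive enzymes varied between the same libraries. In RNA1 replicates 1, 2 and 3 the median ribosomal protein lay at log2 0.031, 0.217 and 0.285 above the control mean, and the median of 19 digestive enzymes at -0.108, 1.07 and 2.22. Among these enzymes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.124, or 0.0102 without RNA1 replicate 1), the amylases Amy-p (log2 2.11 ± 0.45) and Amy-d (2.00 ± 0.43), which are close copies, and Mal-B2 (0.92 ± 0.18).

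In RNA1, proteasome subunits did not pass gene by gene, while a few ubiquitin-system and chaperone genes rose. Of all 11081 tested genes 555 rose, a share close to that of the cullin ligase and COP9 genes below. Of 32 subunits of the 26S proteasome, 0 were called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05, although 31 of 32 had a negative fold change with a mean of log2 -0.21. Camera placed the list low (adjusted p = 0.0481, or 0.849 with an estimated correlation, and fry adjusted p = 0.635). The camera adjusted p was 0.0554 with DESeq2 size factors, 0.0657 with a stricter filter and 0.0686 with the replicate block. It was 0.399 without control replicate 2 and 0.601 without RNA1 replicate 2. The list passed without control replicate 1 (0.0443) or 3 (0.00847) and without RNA1 replicate 1 (0.012) or 3 (0.0199). Of 28 cullin ligase and COP9 genes 2 rose (2 adjusted over the list alone), Cul2 by log2 0.76 ± 0.10 (FDR 0.0019) and the cullin modifier Nedd8 by 0.43 ± 0.09. Of 19 ubiquitin genes 3 rose, among them the ubiquitin-ribosomal fusions RpL40 and RpS27A (log2 0.35 and 0.39), and 4 rose adjusted over the list alone. Among 11 proteasome regulators maf-S rose by log2 0.47 ± 0.08 and Keap1, the inhibitor of its partner Nrf2, fell by 0.56 ± 0.11, and 2 rose and 1 fell adjusted over the list alone. Of 21 heat shock genes 4 rose and 1 fell (4 and 1 adjusted over the list alone). Hsp83, the fly Hsp90, went from 603 to 1740 CPM (log2 1.53 ± 0.26, FDR 0.013), and Hsf, the transcription factor of heat shock genes, rose by 0.23 ± 0.06. Hsp70Ba fell by 5.55 on the log2 scale, but reads of the near-identical Hsp70 copies can be split between genes and its value is uncertain. None of these other lists passed camera (adjusted p = 0.43 for cullin ligases, 0.084 for ubiquitin, 0.802 for the regulators and 0.138 for heat shock, or 0.0411 for heat shock without RNA1 replicate 2). Of 16 oxidative stress genes GstD1 (log2 -0.39 ± 0.10) and GstD2 fell (2 adjusted over the list alone). Their list had a camera adjusted p of 0.0783, or 0.0464 without control replicate 1 and 0.00643 without RNA1 replicate 3.

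Across all 11081 genes, 1137 differed between RNA1 and control at an FDR under 0.05. In RNA1 555 were higher and 582 lower, of which 192 and 110 differed at least 2-fold. Besides the immune genes, those the naming rule took for the size of their change included CG43920, which rose (log2 7.25 ± 1.05), and, among the falls, Hsp70Ba (-5.55 ± 0.65, uncertain as above), the eggshell gene Cp38 (-3.81 ± 0.63), phu (-2.93 ± 0.58), the neprilysin-like Nepl4 (-2.75 ± 0.29), lcs (-1.94 ± 0.28) and the cuticle gene Lcp65Ag2 (-1.65 ± 0.42). CG11349 also fell, from 563 counts over the 3 controls to 5 over the 3 RNA1 libraries, a ratio of control to RNA1 of 99.2 (95% counting interval 42.3 to 307). With any 1 of several libraries left out the count fell to 535, 476 and 548 (control replicates 1, 2 and 3) and 570 (RNA1 replicate 2). With library totals in place of TMM the share of called genes that were higher went from 48.8% to 60.1% (733 higher and 487 lower).

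The comparison of RNA2 with control asks the same of the other knockdown, and immune genes were again among those with large rises. DptA rose to 416 ± 118 CPM (log2 5.66 ± 0.74, FDR 0.016, 2 against 3 libraries). The antibacterial peptide Dro went from 10.3 ± 2.66 to 454 ± 119 CPM (log2 5.47 ± 0.42, FDR 0.0021). IBIN rose by log2 7.19 ± 0.81, edin by 6.27 ± 0.63 and Drs by 3.70 ± 0.16 (FDR 5.4e-06). Of the 33 antimicrobial peptides 19 rose and 2 fell (26 and 3 adjusted over the list alone). Those that fell were Listericin (log2 -0.54) and Drsl4 (-1.44), named after their values were seen. The peptide list passed camera (adjusted p = 7.87e-18; adjusted p = 0.523 with an estimated correlation; fry adjusted p = 0.018). Of 23 Toll and Imd genes 4 rose (7 rose and 1 fell adjusted over the list alone). They were PGRP-SC2 (log2 5.51 ± 0.74), PGRP-SB1 (2.33 ± 0.35), PGRP-SD (1.27 ± 0.25) and the feedback inhibitor pirk (1.81 ± 0.27). Their list passed camera at an adjusted p of 0.0468 (adjusted p = 0.601 with an estimated correlation). Without control replicate 1 or 3 it was 0.057 or 0.0681, and without RNA2 replicate 2 it was 0.253. Of 13 fat body markers Gnmt (log2 2.97 ± 0.37) and Mtp (0.47 ± 0.11) rose and to fell (-0.98 ± 0.12), with 8 rising and 1 falling adjusted over the list alone. The fat body list passed camera (adjusted p = 0.00115; adjusted p = 0.782 with an estimated correlation). Of 12 hemocyte markers Sr-CI (1.28 ± 0.21) and eater (1.36 ± 0.26) rose, and 5 adjusted over the list alone. The hemocyte list passed camera at an adjusted p of 0.0159, or 0.131 without RNA2 replicate 1 (adjusted p = 0.782 with an estimated correlation). In the RNA2 libraries the median antimicrobial peptide lay at log2 1.53 and 1.83 above the control mean and the median fat body marker at 0.623 and 0.383.

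Members of the detoxification, cuticle, glial and oxidative stress lists fell in RNA2. Of 78 cytochrome P450 genes 12 fell and 3 rose (17 and 4 adjusted over the list alone). Cyp6a2 stood at log2 -1.29 ± 0.16, Cyp6d5 at -0.95 ± 0.13 and Cyp6a20 at -0.81 ± 0.11, while Cyp309a2 rose by 1.64 ± 0.19. The P450 list passed camera (adjusted p = 0.00616; adjusted p = 0.601 with an estimated correlation). Of 56 cuticle genes 6 fell and 1 rose (14 and 1 adjusted over the list alone), including Ccp84Ag at log2 -2.30 ± 0.34 and TwdlT at -1.19 ± 0.17. Camera gave the cuticle list an adjusted p of 3.97e-06 (adjusted p = 0.601 with an estimated correlation). Of 16 oxidative stress genes 3 fell (3 adjusted over the list alone), namely GstD2 (log2 -1.80 ± 0.22), GstD1 (-0.49 ± 0.11) and the catalase gene Cat (-0.71 ± 0.14). The oxidative stress list passed camera (adjusted p = 0.00213; adjusted p = 0.782 with an estimated correlation). Of 32 glutathione S-transferases GstD1, GstD2 and GstE3 (-0.95 ± 0.11) fell and GstZ1 rose (0.93 ± 0.17), with 7 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.0882, or 0.0382 without control replicate 1). Of 17 glial genes the astrocyte gene alrm (log2 -0.39 ± 0.08), wrapper (-0.53 ± 0.12), bnb (-0.72 ± 0.16) and zyd (-0.42 ± 0.10) fell, and 6 adjusted over the list alone. Camera gave the glial list an adjusted p of 9.77e-05 (adjusted p = 0.601 with an estimated correlation). Of 22 transmitter genes ChAT fell (log2 -0.37 ± 0.07), and 5 fell adjusted over the list alone. Camera gave the transmitter list an adjusted p of 9.18e-05 (adjusted p = 0.523 with an estimated correlation; fry adjusted p = 0.0377). Of 32 phototransduction genes ninaB fell (-0.54 ± 0.09; 1 adjusted over the list alone; camera adjusted p = 0.177, or 0.0265 without RNA2 replicate 1). EdgeR called 0 of 25 UDP-glycosyltransferases, where 8 had an unadjusted p under 0.05, DESeq2 called 2 higher and 5 lower and limma-voom 0 (camera adjusted p = 0.149, or 0.0471 without control replicate 1 and 0.0381 without RNA1 replicate 2). It also called 0 of 10 activity-regulated genes, where 1 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 (camera adjusted p = 0.177). Of 37 axon guidance, 32 dpr and DIP and 24 synaptic vesicle genes edgeR called 0 each in RNA2. At an unadjusted p under 0.05 there were 4, 5 and 2, DESeq2 called 3, 3 and 0 lower and limma-voom 0. Camera gave these lists adjusted p = 0.0882, 0.0676 and 0.0676, or 0.0275, 0.0496 and 0.049 without control replicate 3. The dpr and synaptic lists also passed without control replicate 2 (0.0362 and 0.0362) or RNA1 replicate 3 (0.038 and 0.0342), and the axon guidance list without RNA2 replicate 2 (0.04998).

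Every subunit of the 26S proteasome had a negative fold change in RNA2 against control, 32 of 32 with a mean of log2 -0.561. Single subunits did not pass, with Prosalpha7 at log2 -0.62 ± 0.21 (FDR 0.173). EdgeR and limma-voom called 0 of 32, 4 had an unadjusted p under 0.05 and 3 were called lower by DESeq2. The list passed camera (adjusted p = 2.92e-08; adjusted p = 0.782 with an estimated correlation; fry adjusted p = 0.331). The library values were uneven, with the median subunit at log2 -1.02 against the control mean in RNA2 replicate 1 and -0.186 in RNA2 replicate 2, beside -0.0666, 0.259 and -0.19 in the controls. Without RNA2 replicate 1 the mean was -0.198. Of 86 cytosolic ribosomal proteins 3 rose (9 adjusted over the list alone), RpS20 (log2 0.40 ± 0.08), RpL21 (0.35 ± 0.08) and RpS3A (0.39 ± 0.09). The ribosomal list had a camera adjusted p of 2.39e-07, or 0.374 without RNA2 replicate 1 (adjusted p = 0.782 with an estimated correlation). The median ribosomal protein lay at 0.381 in RNA2 replicate 1 and 0.0106 in replicate 2, and the median digestive enzyme at 1.75 and 0.0517. Of 19 digestive enzymes Amy-p (2.93 ± 0.48) and Mal-B2 (0.89 ± 0.19) rose (3 adjusted over the list alone; camera adjusted p = 0.257, or 0.0439 without RNA2 replicate 2). EdgeR called 0 of 28 cullin ligase genes (4 at an unadjusted p under 0.05; 0 by DESeq2 or limma-voom) and 0 of 19 ubiquitin genes (6 at an unadjusted p under 0.05; 1 higher by DESeq2, 0 by limma-voom), with camera adjusted p = 0.873 and 0.448. Of 21 heat shock genes 0 rose in RNA2 by edgeR and 1 fell (0 and 1 adjusted over the list alone), with 3 at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 0 by limma-voom. The 1 that fell was Hsp70Ba (log2 -5.52 ± 0.78), uncertain because of its near-identical copies, while Hsp83 stood at 0.51 ± 0.28 (FDR 0.378). The heat shock list had a camera adjusted p of 0.248, or 0.0319 without RNA2 replicate 1. EdgeR called 0 of 11 proteasome regulators in RNA2 (3 at an unadjusted p under 0.05; 1 higher and 1 lower by DESeq2, 0 by limma-voom; 1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.273). Tested between the knockdowns, Hsp83 differed by log2 -1.02 ± 0.29 in RNA2 against RNA1 and did not pass (FDR 0.395).

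Across all genes 419 differed between RNA2 and control, with 195 higher and 224 lower in RNA2, of which 110 and 70 differed at least 2-fold. The naming rule added whe, with 1097 counts over the RNA2 libraries and 4 over the controls, a ratio of 474 (95% counting interval 185 to 1742), and CG45080, with 1438 and 1 counts, a ratio of 2485 (445 to 98210). CG11349 fell, from 563 counts over the controls to 1 over the RNA2 libraries, a ratio of control to RNA2 of 326 (58.2 to 12890). Other falls taken for their size were Hsp70Ba, Ccp84Ag and GstD2, described with their lists, Nepl4 (log2 -2.98 ± 0.35), the odorant receptor Or45b (-1.95 ± 0.26, with an antisense gene over it) and lectin-46Cb (-1.52 ± 0.26). The count fell to 253, 206 and 203 without control replicates 1, 2 and 3 and to 115 without RNA2 replicate 1, and the DESeq2 Wald test gave 875. With library totals in place of TMM the share that were higher went from 46.5% to 56.5% (242 higher and 186 lower).

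**Figure D2:**
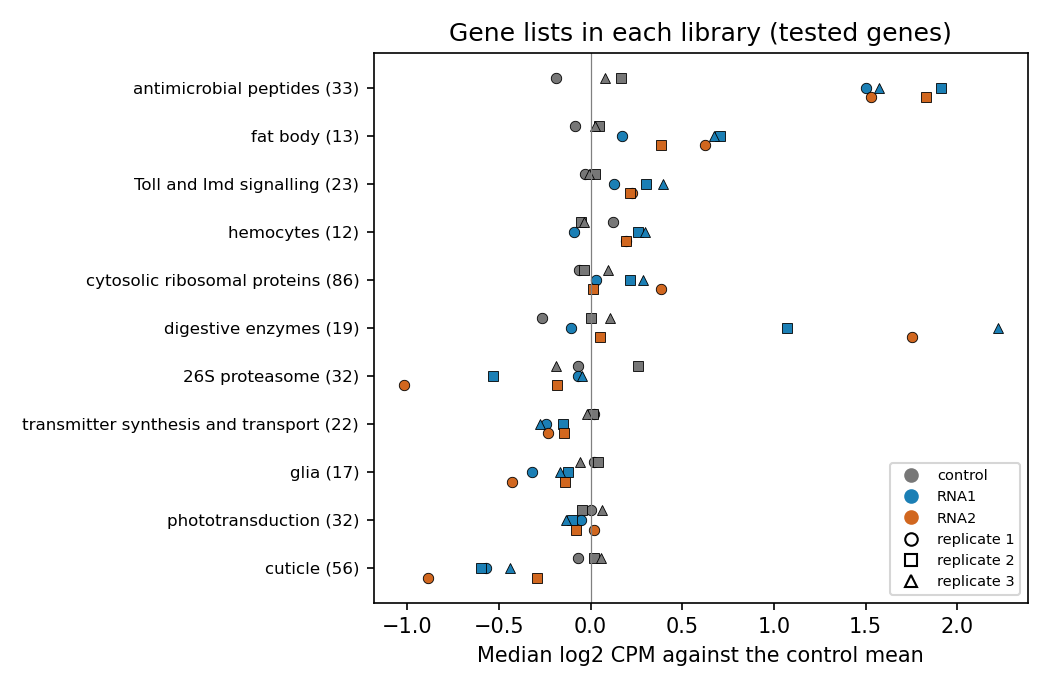
Median log2 CPM of the tested members of 11 gene lists in each of the 8 libraries, relative to the mean of the control libraries (horizontal axis); the number of genes stands in brackets, and colours and symbols give group and replicate. The 5 knockdown libraries lie at 1.5 to 1.91 for antimicrobial peptides, the proteasome median of RNA2 replicate 1 at -1.02, and the digestive enzyme medians between -0.108 and 2.22 in the knockdown libraries.

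In both knockdowns 351 genes differed from control in the same direction, 160 upward and 191 downward. By the naming rule these included, among the rises, Drs, the eye pigment transporter w (from 63 CPM to 245 in RNA1 and 236 in RNA2; log2 1.96 ± 0.09 and 1.91 ± 0.10), which transgenes often carry as a marker, CG18473 (2.11 and 2.18), lncRNA:CR45680 (4.19 and 3.22) and the inositol phosphate kinase gene Ipk1 (0.88 and 1.76). Among the falls were CG31300 (log2 -2.14 in RNA1 and -2.22 in RNA2), CG10553 (-2.29 and -2.53), CG11349, CG6356 (-1.42 and -1.22) and CG34327 (-2.69 and -2.50). Of 3 transgene-linked marker genes, w was the 1 that rose in each knockdown (also 1 adjusted over the list alone). These 351 genes are 83.8% of the 419 called in RNA2, and 1 gene was called in opposite directions, lcs, which fell in RNA1 and rose in RNA2 (log2 -1.94 and 2.69). Independent lists of these sizes would share 9.77 rises and 11.8 falls, and simulated unchanged groups set against the same 3 controls shared 0.1 genes on average and at most 2 in 20 runs. Fold changes over all genes correlated at r = 0.702 (genes are not independent replicates) against 0.431 in the simulation, with covariances of 0.258 and 0.0416, a difference of 0.216. The simulation changed no gene and drew genes independently, so few calls were set in advance and variation common to many genes was left out. It therefore does not measure what the shared controls contribute in these data. The 3 controls could not be split into parts of at least 2 libraries, so part of the overlap may come from the shared controls. The shared count fell to 203, 159 and 159 without control replicates 1, 2 and 3 and to 98 without RNA2 replicate 1, and was 657 with DESeq2; with library totals 199 were higher and 156 lower.

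**Figure D3:**
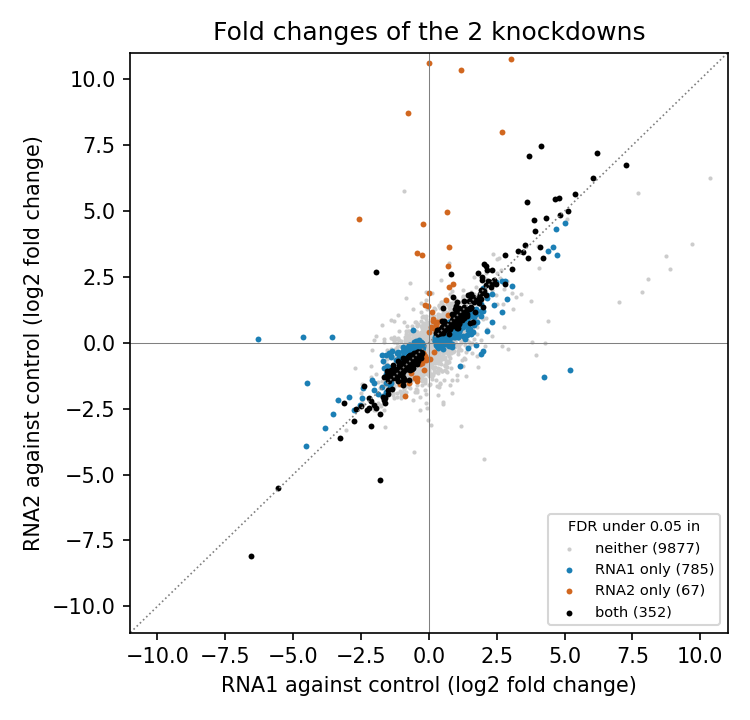
Log2 fold change against control of each of the 11081 tested genes in RNA1 (horizontal axis) and RNA2 (vertical axis), with the dotted line marking equal change. Colours mark genes with an edgeR FDR under 0.05 in both contrasts (352), in RNA1 alone (785), in RNA2 alone (67) or in neither; among the 352, lcs lies at -1.94 in RNA1 and 2.69 in RNA2.

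The direct comparison of RNA2 with RNA1 tests where the knockdowns differ, and edgeR called 31 genes, 21 higher and 10 lower in RNA2. Higher in RNA2 among the genes taken by the naming rule in any contrast was whe, with 1097 counts over the RNA2 libraries and 2 over the RNA1 libraries, a ratio of 835 (95% counting interval 231 to 6905). Another was CG45080 (log2 7.73 ± 0.35), with 1438 counts over the RNA2 libraries but 10 over the RNA1 libraries, so its SE can be too small. Others were the Aurora B kinase gene aurB (log2 4.74 ± 0.37), lcs (4.63 ± 0.29), Ag5r (2.92 ± 0.37), Vajk4 (1.06 ± 0.17) and Ipk1 (0.87 ± 0.08). The antisense RNA asRNA:CR44155 had 0 counts in every RNA1 library and was at least 62.6-fold higher in RNA2, taking 3 counts per library as the floor. Lower in RNA2 by the rule were lncRNA:CR45345, with 603 counts over the RNA1 libraries and 5 over the RNA2 libraries, a ratio of RNA1 to RNA2 of 79.2 (33.8 to 245), kraken (168 ± 36.3 CPM in RNA1 and 47 ± 7.34 in RNA2; log2 -1.84 ± 0.18), the immune genes BaraC (-0.84 ± 0.12) and BomS6 (-0.73 ± 0.11), Cul2 (-0.71 ± 0.11) and Cyp4aa1 (-0.64 ± 0.10). Of these, Ag5r, asRNA:CR44155 and Cyp4aa1 overlap a gene on the opposite strand and lncRNA:CR45345 a gene on its own strand, so reads may have been assigned to either. Cyp4aa1 lost its call whichever single library was left out. In control kraken held 50 CPM, Cul2 125 CPM (211 in RNA1 and 129 in RNA2) and BomS6 87.8 CPM (125 and 74.9). For these and lncRNA:CR45345 (0.149 CPM in control) the control mean lay nearer to RNA2 than to RNA1. For BaraC (21.8 CPM in control, 19.2 in RNA1 and 10.7 in RNA2) and Cyp4aa1 (20.7, 21.2 and 13.6) it lay nearer to RNA1. The 351 genes shared by both knockdowns and the 785 and 67 called in RNA1 or RNA2 alone are otherwise not shown to differ between them. The count was 20 and 19 without control replicates 1 and 3, 18 without RNA1 replicate 2 or 3, 17 without RNA2 replicate 1, and 142 with DESeq2, where the larger part was lower (63 higher and 79 lower).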

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

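The gene list tests between RNA2 and RNA1 and the tests of explanations were chosen after the results they bear on had been seen, namely those of overlapping and neighbouring genes, hemocytes, fat body, infection, a shared exposure or background, and the proteasome medians per library. No group held the 4 libraries that a search for single outlying libraries needs.

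The results singled out here are differences between the knockdowns, found by testing RNA2 against RNA1 directly: 31 genes passed. Those reported here, as log2 fold changes, were CG45080 (7.73), aurB (4.74), lcs (4.63), Ag5r (2.92), Vajk4 (1.06) and Ipk1 (0.87) on the higher side. On the lower side were kraken (-1.84), BaraC (-0.84), BomS6 (-0.73), Cul2 (-0.71) and Cyp4aa1 (-0.64). For genes with 3 or fewer counts per library on average in one knockdown, the ratio of pooled counts was 835 for whe (RNA2 to RNA1; 95% counting interval 231 to 6905) and 79.2 for lncRNA:CR45345 (RNA1 to RNA2; 33.8 to 245). The antisense RNA asRNA:CR44155 was at least 62.6-fold higher in RNA2 than in RNA1 and at least 71.2-fold higher than in control, both of which had 0 counts. Of the gene lists, 3 passed camera between the knockdowns: 26S proteasome (mean log2 -0.351, adjusted p = 6.3e-06), autophagy and lysosome (mean -0.106, adjusted p = 0.042) and phototransduction (mean 0.0747, adjusted p = 0.036). With an estimated correlation 0 passed (adjusted p = 0.979 for the proteasome), and fry called 0 (adjusted p = 0.995). The number of lists called ranged from 1 to 10 as libraries were left out, and was 1 without control replicate 1 or 2 or RNA1 replicate 3, 10 without RNA1 replicate 1 and 6 without RNA2 replicate 2.

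The genes that differ between RNA2 and RNA1 include several with almost no reads in one knockdown. Of the 31 genes, 6 had a tested partner overlapping on the opposite strand, and 0 of these had a partner called in the same direction. The partners' median absolute log2 fold change was 0.0941, which argues against reads misassigned between strands for these 6. Partners on the same strand were not looked up, so misassigned reads stay open for genes such as dbr and lncRNA:CR45345. A local difference in DNA between the fly lines may account for part of the set. Among the 31 genes, 4 pairs start within 20 kb of each other, against a mean of 0.258 in random sets of tested genes, and 5 of 10000 random sets had as many. These pairs are lcs and whe on X, kraken and lncRNA:CR45345 on 2L, asRNA:CR45822 and asRNA:CR45835 on 3L, and lncRNA:CR46254 and dbr on 2L. Neighbours can also share regulation, and a different response to either construct stays open and untested.

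The antimicrobial peptides were higher in both knockdowns, with list medians of log2 1.5 to 1.91 in the 5 knockdown libraries. More hemocytes are argued against as the whole cause: the peptide median exceeded the hemocyte median by at least 1.27 in every knockdown library, above the SD of that difference among the controls (0.281) and of the marker fold changes in RNA1 (0.649), and 0 of 12 markers reached the peptide median. A larger share of fat body, which makes these peptides, stays open: the smallest such difference was 0.897 (control SD 0.113), less than the SD of 0.954 among the marker fold changes in RNA1, and 3 of 13 markers reached the peptide median in each knockdown, with Lsp2 highest at log2 2.35 and 3.36, while the abundant apolpp stood at 0.52 and 0.35. An infection confined to a single fly culture is argued against. All 5 knockdown libraries, under the genotype entries KD1, KD2 and KD3, lay above the control range of -0.19 to 0.165. Each did so by over 2 SDs of the controls (0.185). Replicates may be technical, so separate infections of a culture for each genotype entry stay open. An exposure or genetic background shared by the knockdown libraries, the lowest of which lay 1.34 above the highest control, cannot be told apart from the knockdown because control and knockdown share no genotype entry, and an immune response to FBXO11 loss in neurons remains a hypothesis.

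The 26S proteasome subunits had a mean log2 of -0.561 in RNA2. This may come from RNA2 replicate 1 alone: the median subunit lay at -0.186 in RNA2 replicate 2, inside the control range of -0.19 to 0.259, and at -1.02 in replicate 1. Without replicate 1 the mean was -0.198, 30 of 32 subunits were still negative and camera gave an adjusted p of 0.0329 (adjusted p = 0.896 with an estimated correlation; fry adjusted p = 0.831), which leaves open whether any shift remained. An effect of the FBXO11 knockdown cannot be excluded or shown, as 3 of the 5 knockdown libraries had a median above the lowest control and overlap of so few libraries does not rule out a shift of the average. Beside RNA2 replicate 1, RNA1 replicate 2 lay below every control, at -0.534. The subunits are strongly correlated with each other (0.967), and the control libraries themselves spread with an SD of 0.232.

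The RNA1 and control libraries make 10 splits into 3 and 3, too few for a share under 0.05; the real split, the 1 with as many calls, gave 1137 genes and the highest other 0. For the 351 genes shared by both knockdowns, 100 of the 560 regroupings into 3, 3 and 2 were drawn. In 2 of 100, the real one included, at least as many genes were shared. The other of these gave 461 and kept the 3 controls together while mixing the knockdown libraries, and the highest in the remaining 98 was 0. The count thus follows the division between control and knockdown libraries rather than that between the knockdowns. Replicates of a group may be technical, so the libraries may not be independent units and chance is not excluded.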

How the results depend on the processing

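The FBXO11 decrease passed under all alternatives run, from log2 -1.41 to -1.32 in RNA1 and -1.20 to -0.96 in RNA2 as libraries were left out. Counts of changed genes moved by over 1.5 times in these cases, given in the order RNA1, RNA2, RNA2 against RNA1 and shared, where moved; the cause was not tested unless the setting itself is stricter or uses fewer samples. The DESeq2 Wald test gave 875 (RNA2), 142 and 657. A 2-fold minimum gave 302, 180 and, shared, 132. An FDR under 0.01 gave 346, 141, 15 and 109. With RNA1 replicate 3 and RNA2 replicate 1 both left out, a setting added after seeing the data because these libraries stood apart in digestive enzymes and proteasome subunits, RNA2 gave 153, RNA2 against RNA1 14 and shared 130. Leaving out each library in turn gave 476 to 1189, 115 to 561, 17 to 40 and 98 to 392. An RNA2 group of 1 library was then assumed to vary like the other groups. Gene lists called ranged over 13 to 18 in each knockdown and 1 to 10 between them; an estimated correlation left 0, 0 and 0, and fry 5 in RNA1, 4 in RNA2 and 0 between them.

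The labels do not say whether replicate numbers mark a shared day, so they were not taken as pairs. The deviations of same-numbered libraries correlated at -0.0376, -0.082 and -0.0276 (control and RNA1). They correlated at 0.0375 and 0.164 (control and RNA2) and -0.231 and -0.164 (RNA1 and RNA2). The 2 RNA2 libraries deviate from their own mean by equal and opposite amounts, so the values with RNA2 cannot show pairing. The replicate block gave 773 calls in RNA1, 214 in RNA2, 17 between them, 179 shared and 20 lists in RNA2, and no control correlated best with its own number in RNA1. Of 199 calls on named genes, 105 held in every leave-out, 160 wherever tested with another scaling, filter, test or choice of groups or abundant genes, and 136 with the replicate block; none changed sign. Of the named genes that had not passed, some changed sign as libraries were left out. In RNA2 against control Ugt35C1 ranged from -0.416 to 0.021, Teh3 from -0.16 to 0.031, kraken from -0.26 to 0.057 (0.014 with the block) and lncRNA:CR45345 from -2.32 to 0.128. In RNA1 against control aurB ranged from -0.54 to 0.24 and Cyp4aa1 from -0.020 to 0.082; the cause was not tested. No scaling moved the median of all genes by over 0.04 log2. At these depths the simulated test recovered 49.3% (RNA1) and 39.3% (RNA2) of 1.5-fold changes, so small changes were often missed.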

Other observations

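The tests of gene lists in this part were planned; genes outside the naming rule are marked as chosen after their values were seen. Of 30 odorant-binding proteins 4 fell in RNA1, Obp44a (log2 -0.92 ± 0.09), Obp56d (-0.82 ± 0.08), Obp99d (-1.46 ± 0.24) and Obp19d (-0.42 ± 0.11), and in RNA2 the first 3 of these fell (-0.78, -0.70 and -1.45) and Obp56h rose (0.60 ± 0.12); adjusted over the list alone 4 fell in RNA1, and 6 fell and 3 rose in RNA2. The odorant-binding list did not pass camera (adjusted p = 0.239 and 0.177), and in RNA1 its median and mean differed in sign (log2 -0.0746 and 0.111). Of 63 chemosensory receptors the ionotropic receptors Ir75a (log2 2.15 ± 0.18 in RNA1 and 2.75 ± 0.19 in RNA2) and Ir75b (1.95 ± 0.19 and 2.39 ± 0.21) rose and Or45b fell (-1.51 and -1.95), with the same counts of 2 and 1 adjusted over the list alone. The receptor list passed camera in both (adjusted p = 0.0455 and 0.0159; adjusted p = 0.458 and 0.523 with an estimated correlation), and lost the call in RNA1 without RNA1 replicate 1 (0.0764) or 2 (0.0548) and in RNA2 without RNA2 replicate 1 (0.0692).

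Peptide hormones changed in both directions. Of 38 neuropeptide genes 4 rose and 5 fell in RNA1 (4 and 6 adjusted over the list alone). Ilp6, an insulin-like peptide, rose in both knockdowns (log2 1.23 ± 0.08 in RNA1 and 1.06 ± 0.09 in RNA2), as did the nutrient-dependent peptide CCHa2 (0.56 ± 0.09 and 0.69 ± 0.10), and these were the 2 that rose in RNA2 (2 rose and 1 fell adjusted over the list alone). The list did not pass camera in either (adjusted p = 0.798 and 0.696), and in RNA1 camera placed it low although its median and mean were above 0 (log2 0.012 and 0.040). Nplp1 fell in RNA1 (-0.36 ± 0.07). Su(H), the transcription factor of Notch signalling, fell in both (log2 -0.68 ± 0.08 and -0.46 ± 0.10), 1 of 10 Notch genes (2 and 1 adjusted over the list alone; camera adjusted p = 0.0481 and 0.0111; adjusted p = 0.738 and 0.601 with an estimated correlation). The Notch list lost its call in RNA1 when any of 6 libraries was left out, with adjusted p from 0.0518 to 0.161 (control replicates 1 and 3, RNA1 replicates 1 and 2 and both RNA2 replicates). Of 32 excitability channels Ork1 (-0.77 and -0.67) and Irk3 (-0.52 and -0.64), both potassium channels, fell in both knockdowns, and in RNA1 Teh3 fell (-0.34) and Teh4 rose (0.42); adjusted over the list alone 3 fell and 1 rose in RNA1 and 2 fell in RNA2, and the list did not pass camera (adjusted p = 0.0648 and 0.51; in RNA1 0.0383 without control replicate 2, 0.012 without RNA1 replicate 1 and 0.0299 without RNA1 replicate 2). For 3 homologues of reported FBXO11 substrates, Blimp-1, p53 and l(2)dtl, edgeR called 0 in either knockdown, with 1 at an unadjusted p under 0.05 in RNA1 and 0 in RNA2; DESeq2 called Blimp-1 lower in RNA1, and limma-voom called 0.

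Digestive enzymes were uneven between replicates. In RNA1 replicate 3 the proteases Jon65Aiv, epsilonTry and yip7 held 64.2, 50.4 and 36.5 CPM and the lysozyme LysD 37 CPM, while each lay under 1 CPM in the other 7 libraries; these genes were chosen after their values were seen. Lsp2, a fat body storage protein, held 31.6, 38.7 and 65.8 CPM in the controls, 142, 285 and 268 CPM in RNA1, and 720 and 214 CPM in RNA2, without passing edgeR's test in either knockdown (FDR 0.059 and 0.0501), while DESeq2 called it in both.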
